A study of Mus musculus with 12 samples.

How the data were processed

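RNA-seq of mouse ovary was analysed in 12 libraries, 3 each of Control, MCA205, MCA205_PD1 and MCA205_VAC, taken as groups from the sample titles. The labels describe total RNA extracted with TRIzol and a stranded mRNA library kit, and give no batch or date. The authors deposited one table of RPKM values, with 34881 gene rows. Per the submitters' processing notes, Trimmomatic 0.36, featureCounts from Subread 1.5.1, edgeR 3.12.1 and the mm10 genome were used; the aligner, the annotation and the strand setting of the counting are not given in the sources used here. Dividing each value by what 1 read is worth at that gene length and library gave whole reads, within a tolerance of 0.1, for 100% of the values in every library, so the depth and the reads behind a value could be read back. Counting error is largest for rows with few reads, and the read totals are therefore given for the chemokine genes.

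Symbols were compared with the GENCODE M21 annotation of the same build. Of the rows, 33224 had a symbol in it, 33219 of these on the same chromosome and 33208 with an overlapping span. There were 26 rows with date-like names left by a spreadsheet, 2 names on more than 1 row, and 2562 rows shorter than 200 bp. Overlapping genes, antisense pairs and near-identical paralogs may share or split reads and are uncertain. Cxcl11 is classed as a polymorphic pseudogene in GENCODE M21, and its span overlaps Art3 and Gm2673. Of the 540 genes listed, 535 were in the table.

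Values were tested as log2(RPKM + 0.5), so fold changes are on that scale and understate the change of low genes. Genes with at least 0.5 RPKM in at least 3 libraries were kept, which left 18260. All 12 libraries entered 1 fit of limma 3.58.1 in R 4.3.3 with a variance trend (8 residual and 2.62 prior degrees of freedom), and 6 comparisons were made, 4 of them main ones. The p-values are two-sided and were adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. The median standard error of a log2 fold change was 0.143. Genes under the filter were compared by exact two-sided permutation of 3 against 3. Correlations over libraries used 100000 permutations.

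Before the data were examined, 36 gene lists were fixed, covering interferon response and antigen presentation, immune cells, ovarian cell types, steroid and cholesterol metabolism, stress responses, and other tissues that a dissected ovary could carry; 32 had at least 3 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with the other genes. The same test with an estimated correlation, and limma's fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were alternatives. Camera's preset correlation is small beside the correlations estimated for several of these lists, so its p-values assume more independence between genes than these libraries show.

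Genes were named by a rule also fixed at that time. It takes Cxcl9, Cxcl10, Cxcl11 and Cxcr3; up to 10 rising and 10 falling genes past the threshold with separate groups and a mean of at least 1 RPKM; up to 4 passing members of each list past the threshold or, where none passed, its 2 most abundant members; and, where fewer than 10 genes passed, the 10 with the smallest p. Clone names and variable segments were left out. For the comparisons with Control it takes Cxcl10 and up to 5 genes each way past the threshold. Other genes, such as members passing adjusted over the list alone, were chosen after their values were seen. Some genes that the rule or a list takes are not reported here.

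The alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter, a mean of at least 1 RPKM, median-ratio scaling, quantile normalization, no variance trend, a robust prior, array weights, only the 2 groups compared, a minimum absolute log2 fold change of 1, the replicate number as a block, the other list tests and leaving out each library. Chosen after seeing the data were voom on the reads read back, the corpus luteum score as a covariate, protein-coding rows of at least 200 bp, and the replicate number as a block in a fit of Control and MCA205_VAC alone. The residuals of the same-number libraries of these 2 groups correlated in all 3 pairs (r = 0.371, 0.302 and 0.344), so the numbers may pair them. The labels say nothing of a pairing, and these groups were picked from the data after the other block fit had been seen. Residuals of 3 libraries around their group mean are not independent, so the 3 values do not establish it. In the other 5 comparisons at least 1 pair was below 0.1. Tests made for counts were conditional on the table also holding counts; it holds RPKM only, and they were not run.

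The steps were tested on simulated data made from the real means and depths, with 200 genes changed. Each gene was given the median spread of genes of like abundance, so the shares below do not hold for genes that vary more. At the 10th percentile of that spread, 59.7% of genes changed 1.5-fold were found for MCA205 against Control. Among the real genes, Hba-a1 had a log2 fold change of 3.02 in that comparison without passing (limma adjusted p = 0.157). For MCA205 against Control, with 18145 genes tested, 40.3% of genes changed 1.5-fold were found, 55.2% at 2-fold and 90.4% at 4-fold. For the vaccine against MCA205, with 18161 genes, the shares were 41.4%, 57.4% and 91.9%, for the antibody against MCA205, with 18179 genes, 42.1%, 61.8% and 79.6%, and for the vaccine against the antibody, with 18160 genes, 38.7%, 73.6% and 93.4%. All 3 shifted lists were found in each comparison and none without a shifted gene was called. Simulated genes varied independently, unlike genes in these libraries, so this does not test the list tests under the correlation that real genes have. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.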

Results

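Ovary RNA was profiled in 12 mouse libraries that fall into 4 groups of 3. The groups were a Control group, a group carrying MCA205 tumours, and 2 groups with the same tumour and an immunotherapy. MCA205 is a transplantable mouse fibrosarcoma line, injected under the skin in this series. One treated group, MCA205_PD1, received a monoclonal antibody against the T cell checkpoint receptor PD-1, and the other, MCA205_VAC, received a vaccine made of whole tumour cells. The series title names the chemokine CXCL10 and ovarian function under the vaccine. The depth, read back from the table, ranged from 37801746 assigned reads in MCA205 replicate 3 to 47388647 in MCA205_VAC replicate 3, and between 26265 and 27537 genes had reads in a library. Mitochondrial genes took between 2.96% and 5.08% of the reads. Expression levels are RPKM, reads scaled to gene length and library total, as mean ± SD with n = 3 per group unless stated otherwise. The labels do not say whether the replicates came from separate animals, so every p-value measures only the spread between these samples, which may not be that between animals. Within groups, read counts of 2 libraries differed with a chi-square per gene of at least 12.96. That is more than counting error alone gives, which argues against repeat sequencing of a single library.

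Libraries of 1 group were hardly more alike than libraries of different groups. Across genes, which are not independent replicates, the median Pearson r of log2 values was 0.978 over 12 pairs within groups and 0.977 over 54 pairs between groups. Markers of the corpus luteum, the steroid-secreting gland left after ovulation, varied widely, also inside groups. Their mean log2 score ran from -1.71 in MCA205 replicate 2 to 1.24 in Control replicate 2, and the level of Star, the carrier of cholesterol into mitochondria, ran from 12.4 to 417 RPKM across the 12 libraries. Cholesterol synthesis and uptake genes followed this score (Pearson r = 0.865, Spearman rho = 0.881, permutation p = 0.0001 and 0.00029, adjusted 0.00055 and 0.00121 over a family of 11 relations; r = 0.813 without the 2 libraries farthest from the median score). Oocyte genes moved against it (r = -0.862, rho = -0.916, permutation p = 0.00026 and 0.00011, adjusted 0.000953 and 0.00121; r = -0.857 without those 2 libraries). Endothelial genes moved with it (r = 0.732, rho = 0.783, permutation p = 0.00702 and 0.00395, adjusted 0.0193 and 0.0109). For theca genes r was -0.721 (adjusted p = 0.0206) and for primordial follicle and germ cell genes -0.891 (adjusted p = 0.00055). MCA205 replicates 1 and 2 had luteal scores of -0.96 and -1.71 and replicate 3 had 0.43, so the comparisons of cholesterol, steroid, luteal and oocyte genes stand beside this spread.

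**Figure D1:**
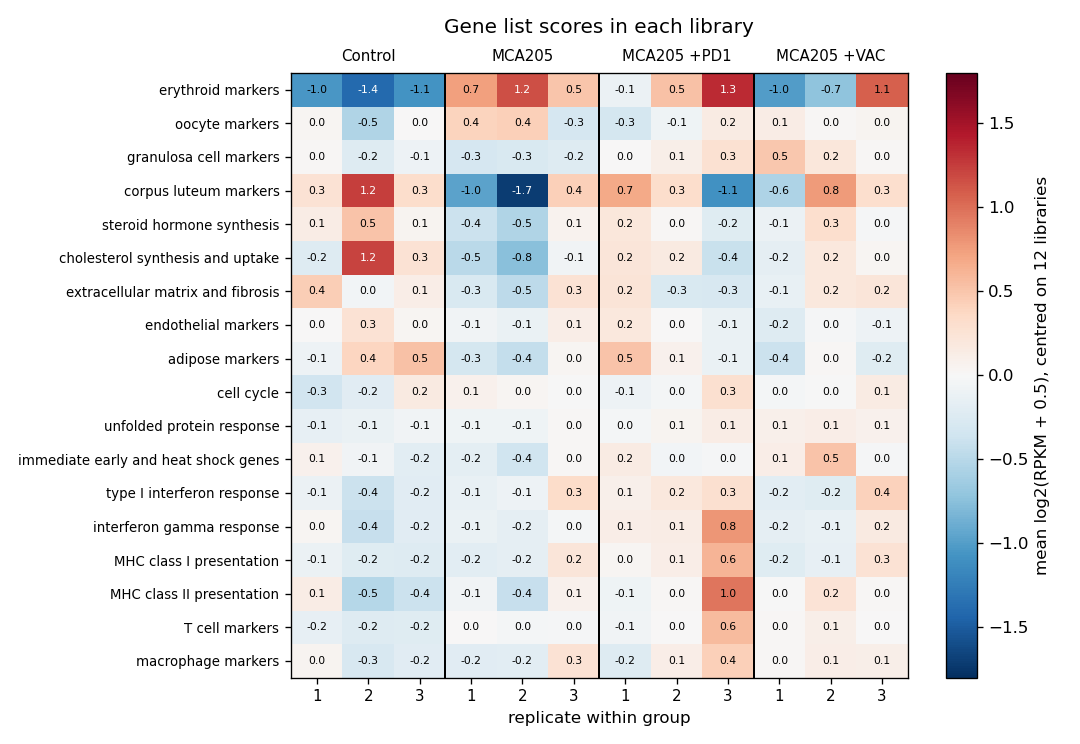
Mean log2(RPKM + 0.5) of 18 of the fixed gene lists in each of the 12 libraries, centred on the mean of the 12, with the replicate number on the horizontal axis and colour and printed numbers giving the score. Corpus luteum scores run from -1.71 to 1.24 and differ widely inside the MCA205 group, and the interferon gamma and MHC class II lists are highest in MCA205_PD1 replicate 3.

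The comparison of MCA205 with Control asks how a distant tumour relates to the ovarian transcriptome. Hba-a1, an alpha globin gene, had 60.9 ± 15.02 RPKM in tumour-bearing mice against 7.02 ± 1.63, and Hbb-bs, a beta globin gene, had 66.0 ± 20.4 against 9.50 ± 3.19. Neither passed over all genes (limma adjusted p = 0.157 and 0.164). Genes of cholesterol synthesis and uptake lay lower in 18 of 19 measured members, with a mean log2 fold change of -0.85. Corpus luteum markers lay lower in 12 of 13 members, with a mean of -1.35, and Cyp11a1, which makes the first step from cholesterol to steroids, had 216 ± 147 RPKM against 464 ± 203. Cxcl10, the ligand in the series title (mm10 chromosome 5, 92346638 to 92348889, minus strand), had 0.237 ± 0.113 RPKM in MCA205 and 0.247 ± 0.060 in Control. It overlaps Art3 on the opposite strand, and the strand setting of the counting is not given in the sources used here, so reads of the 2 genes may not be told apart.

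Of 18260 genes tested, 0 rose and 1 fell in limma's moderated test at an adjusted p of 0.05, while 2972 had an unadjusted p under 0.05 against 913 expected by chance. The gene that fell was Mir6914, a microRNA row of 69 bp on chromosome 10 of mm10 from 128382838 to 128382906, at 1.98 ± 0.278 RPKM against 5.87 ± 0.432 (log2 fold change -1.36, SE 0.12, adjusted p = 0.00497). The row lies inside Ankrd52 on the same strand, in an intron except for its last 6 bases, which fall in an exon from 128382901 to 128382983, so its reads cannot be separated from those of the host transcript. It rests on 17 reads over the 3 MCA205 libraries and 50 over the 3 Control libraries, and Ankrd52 itself had a log2 fold change of -0.36 (SE 0.07, adjusted p = 0.148). The voom method on reads read back from the table called 0 genes. Array weights gave 1569 (1033 higher and 536 lower), with a weight of 7.43 for MCA205 replicate 1, 0.891 for replicate 2 and 0.296 for replicate 3. The weights were estimated from these same libraries. Corpus luteum scores of the 3 were -0.96, -1.71 and 0.43, so the weighted MCA205 mean rests mainly on a library with a low luteal score. The value ranges of the groups did not overlap for 18.8% of genes, where chance gives 10%. Genes vary together in these libraries, so both counts can lie far from the chance values without a group effect. The spread of the chance values was not worked out, here or in the other comparisons.

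Of 32 gene lists, 10 passed limma's camera test with its preset correlation between genes, and 0 of them passed with an estimated correlation (adjusted p = 0.812 for each). The erythroid list rose as a set (7 of 7 members higher, median log2 fold change 2.70, adjusted p = 1.66e-05 with the preset correlation). Adjusted over the list alone, 6 of its members passed, among them Hba-a1, Hba-a2, Hbb-bs, Hbb-bt and Bpgm; the globin genes are near-identical pairs whose reads the counting may have split. The cholesterol list fell (adjusted p = 6.24e-09), and 2 members passed adjusted over the list alone. Among them was Srebf2, the transcription factor that drives the pathway, at 4.37 ± 1.07 RPKM against 7.91 ± 1.04. Members passing over a list alone are named here and below because their values were seen. The most abundant members were Hmgcs1, at 37.0 ± 20.3 RPKM against 92.6 ± 66.2, and Fdft1, at 24.6 ± 1.83 against 34.1 ± 15.2. The corpus luteum list fell (adjusted p = 0.000961), as did the steroid hormone synthesis list (13 of 17 lower, mean -0.52, adjusted p = 0.0248), which shares Cyp11a1 and Hsd3b1 with it; Hsd3b1 had 1487 ± 541 RPKM against 2061 ± 529.

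Oocyte markers rose as a set in MCA205 (19 of 21 higher, mean log2 fold change 0.34, adjusted p = 0.00336). Npm2 and Dppa3, both stored in the egg, had 84.3 ± 24.9 against 59.2 ± 13.4 RPKM and 63.0 ± 17.9 against 39.9 ± 10.2. The type I interferon list rose (24 of 28 higher, mean 0.27, adjusted p = 0.00796), and its 1 member past the threshold over the list alone was the antiviral GTPase Mx2, at 1.53 ± 0.182 RPKM against 0.768 ± 0.106. Bst2, its most abundant member, had a lower mean in MCA205, at 72.7 ± 17.4 against 86.9 ± 23.1 RPKM. Cell cycle genes rose by little (22 of 24 higher, mean 0.16, adjusted p = 0.0115), with Mki67 at 95.7 ± 2.94 against 83.4 ± 19.1 and Top2a at 50.5 ± 3.75 against 46.1 ± 11.02. Pcna was the 1 member past the threshold over that list alone, at 38.4 ± 2.03 against 28.9 ± 2.91. Extracellular matrix genes fell (17 of 19 lower, mean -0.34, adjusted p = 0.0115), with Sparc at 206 ± 99.6 against 290.0 ± 46.2 and Acta2 at 202.6 ± 46.8 against 202.4 ± 32.2. Adipose markers fell (10 of 11 lower, mean -0.51, adjusted p = 0.0248), with Plin4 at 3.67 ± 3.53 against 40.6 ± 57.1 and Pnpla2 at 11.6 ± 2.34 against 12.2 ± 0.632. Antioxidant genes fell (13 of 18 lower, mean -0.24, adjusted p = 0.0386), with Sod1 at 759 ± 81.2 against 824 ± 130 and Gpx3 at 206 ± 108 against 396 ± 77.4. Limma's fry test passed 1 list that camera did not, the skeletal muscle markers (mean 0.27, adjusted p = 0.0170 by fry and 0.148 by camera).

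Among the 10 genes with the smallest p, the other 9 stayed above the threshold, with adjusted p from 0.134 to 0.148. They included Nop58 and Nop56, core proteins of the particles that guide RNA methylation, at 32.8 ± 3.07 against 22.2 ± 1.003 RPKM and 71.2 ± 6.06 against 51.1 ± 1.66. Snrpd1, a core splicing protein, had 260.5 ± 16.2 against 184 ± 14.9, and Nhej1, a DNA end-joining factor, had 4.38 ± 0.292 against 2.40 ± 0.356. The small nucleolar RNA rows Snord73a and Snord91a had 6.80 ± 0.749 against 2.12 ± 0.567 and 8.89 ± 0.726 against 5.65 ± 0.128, and both lie inside protein-coding genes, Rps3a1 and Tsr1. Lower in MCA205 were Usp46os1 (4.18 ± 0.845 against 8.82 ± 1.11), Rassf8 (7.81 ± 0.773 against 12.4 ± 0.830) and the peptidase gene Nrd1 (34.6 ± 0.872 against 46.8 ± 2.58). Cxcl9, another ligand of the receptor CXCR3, had 0.528 ± 0.189 RPKM in MCA205 and 0.426 ± 0.145 in Control (log2 fold change 0.15, SE 0.53, adjusted p = 0.912), and Cxcr3 had 0.190 ± 0.076 and 0.296 ± 0.063. Cxcl10, Cxcl11 and Cxcr3 lay under the filter and have exact two-sided permutation tests of 3 against 3 instead, whose smallest possible p is 0.1; p was 1 for Cxcl10, 1 for Cxcl11 and 0.2 for Cxcr3. Adjusted over its list alone, Inhba also passed, at 35.2 ± 16.9 RPKM in MCA205 against 167 ± 108 in Control (log2 fold change -2.13, SE 0.51, limma adjusted p = 0.154 over all genes), as did Igkc, an immunoglobulin light chain gene, at 2.31 ± 0.495 against 1.33 ± 0.342. Their granulosa and B cell lists did not pass camera (adjusted p = 0.394 and 0.294). Leaving out MCA205 replicate 3 raised the number of changed genes to 123 (87 higher and 36 lower), and leaving out Control replicate 1 or 3 lowered it to 0. Without MCA205 replicate 1 or 2, 4 and 5 lists passed. The erythroid, cholesterol and corpus luteum lists were the 3 of 10 that passed in all 12 leave-one-out fits, and the other 7 each lost the call without at least 1 of the Control or MCA205 libraries. The mean of the cholesterol list was -0.85 with all libraries and -0.45 without Control replicate 2, and that of the corpus luteum list -1.35 and -0.87 without MCA205 replicate 2. Without MCA205 replicate 3 the type I interferon mean was 0.12 (adjusted p = 0.573), and with array weights it was 0.11 (0.533). The scores of MCA205 replicates 1 to 3 on that list were -0.13, -0.096 and 0.32. Oocyte markers had a mean of 0.15 without Control replicate 2 (adjusted p = 0.195) and 0.22 without MCA205 replicate 2 (0.0713). Cell cycle genes had 0.056 without Control replicate 1 (0.457). Matrix genes had -0.20 without Control replicate 1 (0.254) and -0.18 without MCA205 replicate 2 (0.247). For antioxidant genes it was -0.16 without MCA205 replicate 2 (0.226), for steroid synthesis -0.39 (0.161), and for adipose markers -0.38 without Control replicate 3 (0.284). Leaving out MCA205 replicate 3 gave larger means for oocyte (0.58), matrix (-0.55) and antioxidant genes (-0.37), as did Control replicate 3 for cell cycle genes (0.30). With median-ratio scaling the steroid, antioxidant and adipose lists had adjusted p of 0.0695, 0.0695 and 0.0588. A mean of at least 1 RPKM gave 0.0630 for antioxidant and 0.0951 for adipose genes, no filter 0.107 for adipose genes, and protein-coding rows alone 0.0602 for antioxidant genes.

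Vaccinated ovaries were compared with MCA205 ovaries to ask what the vaccine changed in tumour-bearing mice. Granulosa cell genes lay higher with the vaccine, led by Inhba (chromosome 13, 16011851 to 16027211), which encodes the beta-A chain of activin and inhibin, at 253 ± 139 RPKM against 35.2 ± 16.9 (log2 fold change 2.80, SE 0.51), where Control had 167 ± 108. Follistatin, Fst, which binds activin, had 84.0 ± 16.9 against 46.0 ± 2.19. Heat shock chaperones lay higher as well, with Hsph1 (chromosome 5, 149614287 to 149636376) at 76.2 ± 8.75 against 46.7 ± 3.40 and Hspa1b at 33.0 ± 5.45 against 12.9 ± 6.25. Cholesterol genes lay higher in 18 of 19 members. Cxcl10 had 0.222 ± 0.09999 RPKM with the vaccine and 0.237 ± 0.113 without it, from 70 and 66 reads in all (exact permutation p = 1, where 0.1 is the smallest possible). Its log2 fold change was -0.028, and 0.17 with array weights.

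No gene passed limma's test here with equal weights (0 of 18260, lowest adjusted p = 0.121), 1280 genes had an unadjusted p under 0.05, and voom called 0. Array weights gave 1098 (316 higher and 782 lower), with the same weights for the MCA205 libraries. The 10 smallest p values belonged to Mir6914 (4.38 ± 0.453 against 1.98 ± 0.278 RPKM), Snord73a (1.90 ± 0.798 against 6.80 ± 0.749), Hsph1, Fst, Inhba and 5 more genes. These were the co-chaperone Dnaja1 (71.5 ± 4.17 against 52.4 ± 0.691), the zinc finger gene Zfp970 (9.71 ± 0.235 against 13.9 ± 1.49), the chaperone Hspa4l (4.81 ± 0.049 against 3.38 ± 0.090), Trak2 (11.2 ± 0.615 against 8.89 ± 0.236) and the guidance receptor Robo1 (10.8 ± 0.875 against 6.49 ± 1.56). Their adjusted p ran from 0.121 to 0.572. Of the other CXCR3 genes, Cxcl9 had 0.629 ± 0.106 with the vaccine (adjusted p = 0.962), Cxcr3 had 0.209 ± 0.055 (exact permutation p = 0.9) and Cxcl11 had 0 reads in the 3 vaccine libraries and 3 in the MCA205 libraries (exact permutation p = 0.4). Ranges did not overlap for 13.5% of genes, where chance gives 10%.

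Of 32 lists, 7 passed camera with the preset correlation and 0 with an estimated one. The granulosa list rose (12 of 16 higher, mean 0.51, adjusted p = 8.96e-05, and 0.199 with an estimated correlation), and Inhba and Fst were its 2 members past the threshold over the list alone. The inhibin subunits Inha and Inhbb, its most abundant members, had 849 ± 150.5 against 691 ± 25.1 RPKM and 214.5 ± 71.0 against 118 ± 30.5. Immediate early and heat shock genes rose (11 of 15 higher, mean 0.37, adjusted p = 0.00015, and 0.539 with an estimated correlation). Over that list alone 4 members passed, Hsph1, Hspa1b, Hspa1a and Dnajb1, all of them chaperones, with Hspa1a and Hspa1b a near-identical pair, while the immediate early gene Jun had 39.2 ± 13.1 against 31.4 ± 11.2. The unfolded protein response list rose by a small amount (9 of 13 higher, mean 0.14, adjusted p = 0.00164, and 0.199 with an estimated correlation), with Calr at 1471 ± 91.0 against 1178 ± 144 and Hsp90b1 at 1086 ± 97.6 against 904 ± 31.5. The cholesterol list rose (mean 0.46, adjusted p = 2.34e-05), with Hmgcs1 at 51.4 ± 18.5 against 37.0 ± 20.3 and Fdft1 at 28.5 ± 2.17 against 24.6 ± 1.83. Corpus luteum markers rose (11 of 13 higher, mean 0.92, adjusted p = 0.00342), with Cyp11a1 at 347 ± 140 against 216 ± 147 and Hsd3b1 at 1695 ± 209 against 1487 ± 541. Extracellular matrix genes rose (15 of 19 higher, mean 0.25, adjusted p = 0.00353), with Sparc at 264 ± 65.8 against 206 ± 99.6 and Acta2 at 197 ± 15.4 against 202.6 ± 46.8. Erythroid markers fell (7 of 7 lower, mean -1.02, adjusted p = 0.00269), with Hba-a1 at 33.6 ± 40.8 against 60.9 ± 15.02 and Hbb-bs at 34.0 ± 40.1 against 66.0 ± 20.4. For the cholesterol, luteal, matrix and erythroid lists the adjusted p was 0.868 with an estimated correlation. The interferon gamma list did not pass (12 of 20 higher, mean 0.06, adjusted p = 0.396).

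The single member of the endothelial list past the threshold over that list alone was Plvap, a protein of vessel fenestrae, at 6.05 ± 0.667 against 9.42 ± 0.519 RPKM, and that of the skeletal muscle list was Tnni2, at 1.09 ± 0.251 against 2.83 ± 1.47. Neither list passed camera (adjusted p = 0.342 and 0.144). Without MCA205 replicate 3 the count of changed genes was 7, among them Hspa1a, and 17 lists passed. Without MCA205_VAC replicate 3 it was 1. The granulosa, cholesterol and unfolded protein response lists passed in all 12 leave-one-out fits, with a cholesterol mean of 0.29 without MCA205 replicate 2. The corpus luteum and matrix lists lost the call without MCA205 replicate 1 or 2, and the luteal list also without MCA205_VAC replicate 2. The immediate early and heat shock list lost it without MCA205_VAC replicate 2 and the erythroid list without MCA205_VAC replicate 1. The luteal mean was 0.44 without MCA205 replicate 2 (adjusted p = 0.3196) and 1.51 without MCA205 replicate 3. The matrix mean was 0.097 (0.422) and 0.47 without the same libraries, and 0.38 with array weights. Without MCA205_VAC replicate 2 the immediate early mean was 0.22 (0.0829). The erythroid mean was -0.62 without MCA205_VAC replicate 1 (0.105) and -1.67 without MCA205_VAC replicate 3.

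**Figure D2:**
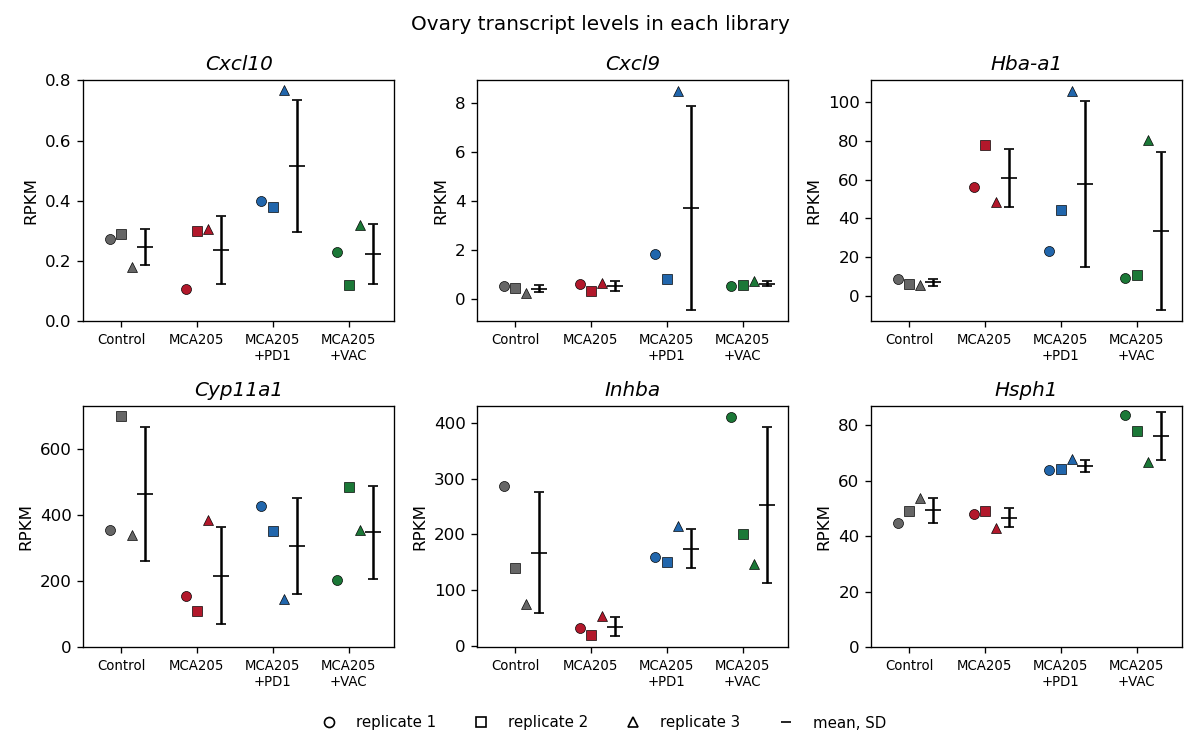
RPKM of Cxcl10, Cxcl9, Hba-a1, Cyp11a1, Inhba and Hsph1 in each of the 12 libraries, by group on the horizontal axis, with 1 symbol per library, a short bar for the group mean and whiskers of 1 SD. Hsph1 lies at 76.2 ± 8.75 with the vaccine and 65.3 ± 2.04 with the PD-1 antibody against 46.7 ± 3.40 in MCA205, and the mean of Cxcl9 with the PD-1 antibody is set by replicate 3.

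PD-1 antibody ovaries were compared with MCA205 ovaries to ask the same of checkpoint blockade. Interferon gamma response genes lay higher with the antibody in 18 of 20 members, with a mean log2 fold change of 0.45. Among them Tgtp2, an interferon-induced GTPase, had 6.48 ± 2.82 RPKM against 2.62 ± 0.171 and its near-identical neighbour Tgtp1 had 2.08 ± 0.603 against 0.917 ± 0.097. Cxcl10 averaged 0.515 ± 0.219 against 0.237 ± 0.113 from 152 and 66 reads, with every antibody library above every MCA205 library (exact permutation p = 0.1, the smallest possible). The fewest reads in an antibody library were 34 and the most in an MCA205 library 30, and 76 of the 152 came from 1 antibody library. Cxcl9 averaged 3.72 ± 4.17 against 0.528 ± 0.189, and replicate 3 alone reached 8.499 (log2 fold change 1.58, SE 0.53, adjusted p = 0.701). Granulosa genes lay higher, with Inhba at 175 ± 34.9 against 35.2 ± 16.9, where Control had 167 ± 108. The MCA205 libraries are the same 3 as in the vaccine comparison, so the 2 results are not independent.

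By limma 0 of 18260 genes passed (lowest adjusted p = 0.688), 1280 had an unadjusted p under 0.05, voom called 0, and ranges did not overlap for 11.1% of genes against 10% by chance. The 10 smallest p values included 3 chaperones, Hsp90aa1 (480.2 ± 44.9 against 342 ± 29.1 RPKM), Hspa4l (4.77 ± 0.262 against 3.38 ± 0.090) and Hsph1, and the endoplasmic reticulum lectin gene Mlec (65.4 ± 5.47 against 49.0 ± 2.04). The circadian gene Per1 had 4.82 ± 0.445 against 7.48 ± 0.396 and the meiotic gene Sycp2l had 1.39 ± 0.371 against 3.04 ± 0.460. Txnrd3 (8.14 ± 0.181 against 10.6 ± 0.228), Fibp (6.60 ± 0.414 against 9.13 ± 1.064) and the microRNA row Mir1905 (33.3 ± 2.45 against 23.6 ± 2.11), which lies inside Mex3a, were among them too. The adjusted p was 0.688 for each of the 10. Cxcl11, classed as a polymorphic pseudogene and overlapping Art3 and Gm2673, had 17 reads against 3 (exact permutation p = 0.1). Cxcr3 had 0.316 ± 0.252 RPKM against 0.190 ± 0.076 (exact permutation p = 0.6).

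Of 32 lists, 12 passed camera with the preset correlation and 0 with an estimated one. The interferon gamma list rose (adjusted p = 3.34e-09, and 0.681 with an estimated correlation), with 2 members, Tgtp1 and Tgtp2, past the threshold over the list alone. Its most abundant members Gbp3 and Gbp2 had 42.1 ± 13.5 against 33.1 ± 13.3 and 23.2 ± 9.56 against 13.3 ± 3.02 RPKM. MHC class I presentation (14 of 16 higher, mean 0.29, adjusted p = 0.000331) and MHC class II presentation (8 of 8 higher, mean 0.43, adjusted p = 0.00168) rose. B2m had 140 ± 33.9 against 122 ± 17.7 and Psme1 164 ± 20.8 against 181 ± 40.5. Of class II, Cd74 was at 87.7 ± 47.0 against 58.7 ± 9.71 and H2-Ab1 at 88.2 ± 49.3 against 50.6 ± 8.71. T cell markers rose (9 of 10 higher, mean 0.19, adjusted p = 0.0301), with Tcf7 at 18.2 ± 2.48 against 17.9 ± 1.60 and Cd4 at 2.05 ± 0.875 against 1.76 ± 0.302. For these lists the adjusted p was 0.681 with an estimated correlation. The type I interferon list rose (21 of 28 higher, mean 0.16, adjusted p = 0.00974, and 0.791 with an estimated correlation), with Bst2 at 86.9 ± 5.02 against 72.7 ± 17.4. In MCA205_PD1 replicate 3 the T cell score was 0.570 where the next library had 0.112. Without it the mean of the T cell list was -0.01 (adjusted p = 0.838), the MHC class I mean was 0.12 (0.0635), the MHC class II mean 0.10 (0.228) and the type I interferon mean 0.11 (0.0749). These calls also ended without an MCA205 library. The adjusted p was 0.0661 for MHC class I, 0.465 for type I interferon (mean 0.079) and 0.0782 for T cell markers without replicate 1. It was 0.0833 for MHC class II, 0.246 for type I interferon (mean 0.095) and 0.111 for T cell markers without replicate 2. Over the settings that keep all libraries, with the preset correlation, the adjusted p ran from 0.00119 to 0.272 for T cell markers, 1.45e-06 to 0.00104 for MHC class I, 0.00114 to 0.0123 for MHC class II and 9.23e-06 to 0.0814 for type I interferon. The interferon gamma list passed without MCA205_PD1 replicate 3 with the preset correlation, at a mean of 0.23 (adjusted p = 7.93e-05, against 1.86e-11 to 2.61e-07 over the settings that keep all libraries and this correlation).

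Granulosa genes rose with the antibody (12 of 16 higher, mean 0.40, adjusted p = 0.000729, and 0.564 with an estimated correlation). Inhba and Fst were the 2 members past the threshold over the list alone, as for the vaccine against the same MCA205 libraries. Inha was at 883 ± 165 against 691 ± 25.1 and Inhbb at 218 ± 51.0 against 118 ± 30.5. Oocyte markers fell (20 of 21 lower, mean -0.25, adjusted p = 0.00176, and 0.752 with an estimated correlation), with Npm2 at 67.8 ± 14.0 against 84.3 ± 24.9 and Dppa3 at 47.0 ± 8.30 against 63.0 ± 17.9. The cholesterol list rose (18 of 19 higher, mean 0.43, adjusted p = 9.65e-05, and 0.681 with an estimated correlation), with Hmgcs1 at 55.9 ± 22.9 and Fdft1 at 27.4 ± 3.71. Corpus luteum markers rose (10 of 13 higher, mean 0.72, adjusted p = 0.0301, and 0.752 with an estimated correlation), with Cyp11a1 at 307 ± 145 and Hsd3b1 at 1706 ± 345. Smaller shifts past the threshold were upward for immediate early and heat shock genes (10 of 15 higher, mean 0.20, adjusted p = 0.0301), where Hsph1 had 65.3 ± 2.04 against 46.7 ± 3.40 and Jun 31.3 ± 6.77 against 31.4 ± 11.2. The unfolded protein response list (9 of 13 higher, mean 0.10, adjusted p = 0.0204) had Calr at 1387 ± 99.8 and Hsp90b1 at 1089 ± 150, and the adipose list (9 of 11 higher, mean 0.39, adjusted p = 0.0433) had Plin4 at 17.7 ± 17.3 and Pnpla2 at 10.3 ± 0.806. With an estimated correlation the adjusted p of these lists was 0.681, 0.669 and 0.681. Leaving out MCA205 replicate 1 or 2 gave 4 lists each, and leaving out MCA205 replicate 3 gave 21. The interferon gamma, granulosa and cholesterol lists were the 3 of 12 that passed in all 12 leave-one-out fits, with a cholesterol mean of 0.27 without MCA205 replicate 2. The other 9 lost the call without MCA205 replicate 1 or 2 or 1 of the antibody libraries. Oocyte markers had a mean of -0.14 without MCA205 replicate 1 (adjusted p = 0.187), -0.13 without MCA205 replicate 2 (0.212) and -0.13 without MCA205_PD1 replicate 1 (0.107). The luteal mean was 0.24 without MCA205 replicate 2 (0.741) and 0.36 without MCA205_PD1 replicate 1 (0.380). For immediate early and heat shock genes it was 0.11 without MCA205 replicate 2 (0.370), for the unfolded protein response 0.057 without MCA205_PD1 replicate 3 (0.0957), and for adipose markers 0.22 without MCA205_PD1 replicate 1 (0.281). Leaving out MCA205 replicate 3 gave means of 1.31 for luteal, -0.49 for oocyte and 0.30 for type I interferon genes, and array weights gave 1.12, -0.51 and 0.28. Without MCA205_PD1 replicate 3 the luteal mean was 1.25, and without MCA205_PD1 replicate 1 the T cell mean was 0.30. Of the 12 settings that keep all libraries and the preset correlation, 5 ended the adipose call, 3 the immediate early call and 2 the luteal call. Their highest adjusted p were 0.342, 0.0592 and 0.0714.

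The direct comparison of the treatments, MCA205_VAC minus MCA205_PD1, asks where vaccine and antibody differ. Interferon and antigen presentation genes lay lower with the vaccine. Of the interferon gamma list 18 of 20 members were lower (mean -0.39), with Gbp2 at 16.1 ± 3.995 RPKM against 23.2 ± 9.56 and Gbp3 at 33.1 ± 8.83 against 42.1 ± 13.5. Cxcl10 had 0.222 ± 0.09999 with the vaccine and 0.515 ± 0.219 with the antibody, without overlap (70 and 152 reads, exact permutation p = 0.1, the smallest possible). The fewest reads in an antibody library and the most in a vaccine library were both 34, so library depth alone parts these libraries. Cxcl9 had 0.629 ± 0.106 and 3.72 ± 4.17 (log2 fold change -1.43, SE 0.53, adjusted p = 1), Cxcl11 had 0 and 17 reads (exact permutation p = 0.1), and Cxcr3 had 0.209 ± 0.055 and 0.316 ± 0.252 (exact permutation p = 0.9).

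Limma called 0 of 18260 genes (lowest adjusted p = 1), 473 had an unadjusted p under 0.05 where chance gives 913, voom called 0, and ranges did not overlap for 8.14% of genes against 10% by chance. Among the 10 smallest p values were 4 rows of short non-coding RNA inside other genes, namely Snord49a (11.2 ± 2.33 against 19.9 ± 2.81 RPKM), Snord14d in the chaperone gene Hspa8 (10.3 ± 3.42 against 22.7 ± 2.93), Snord73a (1.90 ± 0.798 against 3.95 ± 0.554) and Mir1982 (5.25 ± 0.369 against 3.52 ± 0.429). Pigr, the carrier of IgA across epithelia, had 2.10 ± 0.329 against 7.36 ± 5.16, Rn7sk had 0.518 ± 0.248 against 1.81 ± 0.495, and the carboxylesterase gene Ces1b had 0.583 ± 0.0998 against 2.40 ± 1.84. Dnaja1 (71.5 ± 4.17 against 59.8 ± 4.16), Rps14 (146 ± 9.003 against 175 ± 8.496) and Cxxc5 (7.48 ± 0.656 against 5.21 ± 0.924) were the rest.

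Of 32 lists, 10 passed camera with the preset correlation and 0 with an estimated one. The interferon gamma list (adjusted p = 6.01e-10, and 0.736 with an estimated correlation) and MHC class I presentation (15 of 16 lower, mean -0.29, adjusted p = 8.60e-06, and 0.736 with an estimated correlation) fell with the vaccine relative to the antibody. B2m had 114 ± 22.97 against 140 ± 33.9 and Psme1 163 ± 26.2 against 164 ± 20.8. The type I interferon list fell (23 of 28 lower, mean -0.19, adjusted p = 0.00201, and 0.754 with an estimated correlation), with Bst2 at 81.6 ± 7.29 against 86.9 ± 5.02. Erythroid markers (6 of 7 lower, mean -0.81), endothelial markers (13 of 15 lower, mean -0.14) and adipose markers (10 of 11 lower, mean -0.35) each fell at an adjusted p of 0.00369. Hba-a1 had 33.6 ± 40.8 against 57.8 ± 42.8 and Hbb-bs 34.0 ± 40.1 against 67.9 ± 45.3. The endothelial genes Cdh5 and Eng had 21.6 ± 2.48 against 21.2 ± 3.59 and 14.0 ± 1.93 against 15.5 ± 1.54. Plin4 had 8.89 ± 7.89 against 17.7 ± 17.3 and Pnpla2 10.5 ± 0.228 against 10.3 ± 0.806. Acute phase and complement genes fell (9 of 12 lower, mean -0.27, adjusted p = 0.0161), with C1s1 at 47.6 ± 7.42 against 46.6 ± 10.95. Extracellular matrix genes (17 of 19 higher, mean 0.21, adjusted p = 0.00369), oocyte markers (20 of 21 higher, mean 0.15, adjusted p = 0.0045) and immediate early and heat shock genes (9 of 15 higher, mean 0.17, adjusted p = 0.00798) rose. Sparc had 264 ± 65.8 against 215 ± 73.5, Acta2 197 ± 15.4 against 183 ± 30.9, Npm2 73.7 ± 3.77 against 67.8 ± 14.0, Dppa3 50.7 ± 5.12 against 47.0 ± 8.30, Hsph1 76.2 ± 8.75 against 65.3 ± 2.04 and Jun 39.2 ± 13.1 against 31.3 ± 6.77. The adjusted p with an estimated correlation was 0.754 for the matrix and oocyte lists and 0.736 for the erythroid, endothelial, adipose, acute phase and immediate early lists. Without MCA205_VAC replicate 1, 6 lists passed. The interferon gamma and MHC class I lists were the 2 of 10 that passed in all 12 leave-one-out fits. Without MCA205_PD1 replicate 3 their means were -0.17 and -0.11 (adjusted p = 0.00224 and 0.0431). The other 8 each lost the call without at least 1 of the vaccine or antibody libraries. Without MCA205_VAC replicate 1 the mean was -0.091 for type I interferon (adjusted p = 0.267), -0.41 for erythroid (0.239), -0.086 for endothelial (0.229) and -0.18 for acute phase genes (0.164). Without MCA205_VAC replicate 2 it was -0.079 for type I interferon (0.384) and 0.017 for immediate early and heat shock genes (0.859). Without MCA205_PD1 replicate 1 it was 0.026 for oocyte (0.408), -0.062 for endothelial (0.408) and -0.17 for adipose markers (0.156). Matrix genes had 0.12 without MCA205_PD1 replicate 2 (0.329) or 3 (0.134), and erythroid markers -0.43 without MCA205_PD1 replicate 3 (0.233). Means were larger without MCA205_VAC replicate 3 for type I interferon (-0.39), MHC class I (-0.43), erythroid (-1.46) and immediate early genes (0.28). So was the oocyte mean without MCA205_PD1 replicate 3 (0.26), and the matrix mean without MCA205_PD1 replicate 1 (0.38) or MCA205_VAC replicate 1 (0.32). With array weights and with only the 2 groups the erythroid list had adjusted p of 0.0688 and 0.0535, and with a mean of at least 1 RPKM the adipose list had 0.0895.

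Each treated group was also set against Control, to place it beside mice without the tumour. In the vaccine group Cxcl10 had 0.222 ± 0.09999 RPKM against 0.247 ± 0.060 (exact permutation p = 0.7), and with the antibody it had 0.515 ± 0.219, above every Control library (exact permutation p = 0.1, the smallest possible). With the antibody, all 28 tested type I interferon genes lay higher than in Control (mean log2 fold change 0.43) and 19 of 20 interferon gamma genes did (mean 0.55, and 0.32 without MCA205_PD1 replicate 3). Unfolded protein response genes lay higher in both treated groups in 10 of 13 members, with the chaperone Hspa5 at 335 ± 12.7 RPKM with the vaccine and 331 ± 25.1 with the antibody against 252 ± 9.65. Limma called 0 genes in either comparison (lowest adjusted p = 0.145 in both), with 774 and 954 genes at an unadjusted p under 0.05, 0 calls by voom, and ranges that did not overlap for 11.2% and 10.01% of genes, where chance gives 10%.

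Camera passed 14 lists for the vaccine and 13 for the antibody with the preset correlation, and 0 with an estimated one. Vaccine ovaries had higher unfolded protein response genes (mean 0.20, adjusted p = 9.72e-06, and 0.0705 with an estimated correlation; fry adjusted p = 0.0306), with Hspa5, Creld2 and Manf past the threshold over the list alone, and lower endothelial genes (15 of 15 lower, mean -0.22, adjusted p = 3.37e-05, and 0.561 with an estimated correlation). The endothelial mean was -0.14 without Control replicate 2 (adjusted p = 0.0240), and the endothelial score follows the luteal one over the 12 libraries. In antibody ovaries both interferon lists rose (adjusted p = 1.25e-11 each, and 0.371 with an estimated correlation). The MHC class I, MHC class II and T cell lists rose beside them, passing with the preset correlation in all 12 leave-one-out fits. Macrophage markers rose too, but without MCA205_PD1 replicate 3 their mean was 0.098 (camera adjusted p = 0.261). Of the interferon gamma list 7 members passed over the list alone, the highest fold being that of Iigp1, at 7.56 ± 3.72 RPKM against 2.20 ± 0.366, and 3 of the type I list passed, Ifit1, Mx1 and Mx2. Erythroid markers rose in both (7 of 7 higher; mean 0.96, adjusted p = 0.000267 with the vaccine and mean 1.76, adjusted p = 4.24e-08 with the antibody; 0.586 and 0.371 with an estimated correlation), though without MCA205_VAC replicate 3 the vaccine mean was 0.31 (adjusted p = 0.108). The cholesterol list fell in both (mean -0.39, adjusted p = 0.000169 and mean -0.42, adjusted p = 3.08e-05; 0.609 and 0.519 with an estimated correlation). Without Control replicate 2 the mean of the cholesterol list was 0.01 with the vaccine (adjusted p = 0.597) and -0.02 with the antibody (adjusted p = 0.847), and without MCA205_PD1 replicate 3 it was -0.23 with the antibody (adjusted p = 0.0546). Without Control replicate 1 it was -0.72 with the vaccine and -0.74 with the antibody. Over the settings that keep all libraries and the preset correlation the adjusted p ran from 9.13e-06 to 0.00291 and from 4.21e-06 to 0.00369. Without Control replicate 2 or 3, 9 lists passed in the vaccine comparison, and without MCA205_PD1 replicate 3, 7 passed in the antibody comparison. The replicate numbers may pair the Control and vaccine libraries, which the labels do not say. With the number as a block in a fit of these groups, 17 lists passed with the preset correlation. The 3 added to the 14 of the main fit were MHC class I presentation (mean 0.15, adjusted p = 0.0448, and 0.0804 in the main fit), steroid hormone synthesis (mean -0.17, 0.00617 and 0.211) and corpus luteum markers (mean -0.43, 0.000304 and 0.0852). The main fit holds all 12 libraries and no block. These differences therefore mix the block with leaving out the other 2 groups, and cannot be credited to the block alone. With an estimated correlation the block gave them adjusted p of 0.719, 0.627 and 0.627.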

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

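The voom, corpus luteum covariate, protein-coding and 2-group block settings were chosen after the results were seen. Over 205 results and 5207 alternative values, 4918 had the same direction and side of the threshold and 72 reversed, 46 of these on leaving out 1 library and 18 with the corpus luteum covariate. Much of this agreement was fixed in advance. Leaving out a library outside the 2 groups compared cannot move a fold change, also in the leave-one-out fits counted for lists. A gene that passed in neither fit counted as the same when its sign held. For the changes given here the cause was not tested, except that without a filter more genes enter and that a 2-group fit has fewer samples. edgeR and DESeq2 on counts were planned for a table with counts and not run, as the table holds RPKM only; the robust prior and the covariate gave no list values, and voom none for Cxcl10, Cxcl11 and Cxcr3.

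Without a filter limma called 6 genes for MCA205 minus Control, 1 for MCA205_VAC minus MCA205, 2 for MCA205_PD1 minus MCA205, 3 for MCA205_VAC minus MCA205_PD1, 2 for MCA205_VAC minus Control and 4 for MCA205_PD1 minus Control, and 20 lists passed for the last. Without a variance trend it called 3 for MCA205 minus Control and 1 for each treated group against Control. Array weights gave 1569 genes for MCA205 minus Control and 1098 for MCA205_VAC minus MCA205, with a weight of 7.43 for MCA205 replicate 1 and 0.296 for replicate 3, and 15 and 21 lists for the vaccine and the antibody against MCA205. For MCA205 minus Control, 0 genes were called with only the 2 groups, 0 by voom, 0 among protein-coding genes of at least 200 bp and 2 with the covariate. Camera with an estimated correlation passed 0 lists in each of the 6 comparisons. Fry passed 1 list for MCA205 minus Control and 1 for MCA205_VAC minus Control, and 0 in the other 4.

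With the corpus luteum covariate the log2 fold change turned to -0.27 for Cxcl9, 0.059 for Bst2, 0.028 for Hsd3b1, 0.088 for Sod1, 0.13 for Sparc, 0.10 for Acta2, 0.022 for Plin4 and 0.12 for Pnpla2 in MCA205 minus Control. In MCA205_VAC minus MCA205 it was 0.052 for Cxcl10, -0.23 for Hmgcs1, -0.12 for Hsd3b1, -0.023 for Cyp11a1 and -0.061 for Sparc. In MCA205_PD1 minus MCA205 it was -0.011 for Fdft1, -0.042 for Hsd3b1, -0.072 for Cyp11a1 and -0.091 for Jun. In MCA205_VAC minus MCA205_PD1 it was -0.023 for Cdh5. With array weights the log2 fold change turned to 0.17 for Cxcl10, -0.10 for Cxcr3 and 0.032 for Acta2 in MCA205_VAC minus MCA205. In MCA205_PD1 minus MCA205 it was -0.072 for Tcf7. In MCA205_VAC minus MCA205_PD1 it was 0.023 for Psme1 and -0.0028 for Cdh5. With median-ratio scaling the log2 fold change turned to 0.0091 for Acta2 in MCA205_VAC minus MCA205. With quantile normalization the log2 fold change turned to 0.0039 for Psme1 in MCA205_VAC minus MCA205_PD1.

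Leaving out each library in turn gave 0 to 123 genes and 4 to 13 lists for MCA205 minus Control, 0 to 7 and 5 to 17 for MCA205_VAC minus MCA205, 0 and 4 to 21 for MCA205_PD1 minus MCA205, 0 and 6 to 14 for MCA205_VAC minus MCA205_PD1, 0 and 9 to 16 for MCA205_VAC minus Control, and 0 and 7 to 19 for MCA205_PD1 minus Control. The fits assume that the 2 libraries left vary like the other groups. In MCA205 minus Control, the log2 fold change ran from -0.10 to 0.11 for Cxcl10, -0.0028 to 0.019 for Cxcl11, -0.21 to 0.0093 for Sod1 and -0.19 to 0.14 for Acta2. It ran from -0.24 to 0.010 for Pnpla2. In MCA205_VAC minus MCA205, the log2 fold change ran from -0.012 to 0.25 for Cxcl9, -0.16 to 0.079 for Cxcl10, -0.014 to 0.13 for Cxcr3 and -0.17 to 0.16 for Acta2. In MCA205_PD1 minus MCA205, the log2 fold change ran from 0.28 to 0.55 for Cxcl10, -0.036 to 0.35 for Cxcr3, -0.23 to 0.043 for Psme1 and -0.011 to 0.31 for B2m. It ran from -0.060 to 0.13 for Tcf7, -0.13 to 0.32 for Cd4, -0.17 to 0.30 for Jun and -0.010 to 0.30 for the mean of the T cell markers list. In MCA205_VAC minus MCA205_PD1, the log2 fold change ran from -0.58 to -0.31 for Cxcl10, -0.31 to 0.077 for Cxcr3, -0.13 to 0.10 for Psme1 and -0.015 to 0.28 for Npm2. It ran from -0.031 to 0.22 for Dppa3, -0.012 to 0.23 for Acta2, -0.070 to 0.16 for Cdh5 and -0.10 to 0.22 for C1s1. It ran from -1.78 to 0.13 for Plin4 and -0.0010 to 0.10 for Pnpla2. In MCA205_VAC minus Control, the log2 fold change ran from -0.15 to 0.051 for Cxcl10 and -0.72 to 0.0065 for the mean of the cholesterol synthesis and uptake list. In MCA205_PD1 minus Control, the log2 fold change ran from 0.25 to 0.52 for Cxcl10.

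With the replicate block limma called 1 gene for MCA205 minus Control and 0 in the other comparisons, and 10, 7, 13, 10, 15 and 14 lists passed in the 6 comparisons. In the fit of Control and MCA205_VAC alone with the block, 0 genes were called. Every list that passed in the main fit of all 12 libraries also passed there. A pairing in those groups is possible and not established. Over all 18 same-number pairs r ran from -0.34 to 0.37 with a mean of 0.04, against -0.02 for different numbers. Of these pairs 7 were above 0.1, and 6 of 12 libraries correlated best with their own number. The 66 reads of Cxcl10 over the 3 MCA205 libraries carry a counting error of 12.3% of the total.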

Other observations

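Of the tests in this part, the splits of the samples and, for the chaperones, the tests of time of day and of luteal share were chosen before their results were seen, and all others after. The bounds for the study group, single library, lymph node, time of day and dissection stress tests were revised after their values were known. The single-library test replaced an earlier one, in which the interferon gamma list was tested without MCA205_PD1 replicate 3. There it passed camera with the preset correlation (adjusted p = 7.93e-05, against 1.86e-11 to 2.61e-07 over the settings that keep all libraries and this correlation). With an estimated correlation and all libraries it did not pass. A test of library depth against the luteal score was dropped after its Spearman rho of -0.035 was seen.

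A group of 18 chaperones of the cytosol and mitochondria, listed after Hsph1, Dnaja1 and Hspa4l were seen among the smallest p values, differed between MCA205 and treated ovaries. The median log2 fold change was 0.29 for the vaccine against MCA205, with 17 of 18 members higher, and 0.32 for the antibody against MCA205, with 18 of 18 higher. Against Control it was 0.22 for the vaccine (15 of 18 higher), 0.21 for the antibody (16 of 18 higher) and -0.084 for MCA205 (15 of 18 lower), so most of the gap lies between Control and the treated groups. As these genes were listed for the pattern, no test of it is given. Each group was also set against the other 9 libraries for each of the 32 lists. The smallest exact p values were 0.00909 for lower erythroid markers in Control (difference -1.56), and 0.0136 both for lower granulosa markers in MCA205 (-0.36) and for higher interferon gamma genes in MCA205_PD1 (0.46). None of the 128 tests passed adjustment (lowest adjusted p = 0.540).

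Comparisons that share libraries share their chance values. Across 18260 genes, which are not independent replicates, the fold changes of vaccine and antibody against MCA205 had r = 0.642, where 100 simulations of unchanged groups gave a mean of 0.496 and a range from -0.0633 to 0.927, and a covariance of 0.0385 against 0.0295. Against Control the values were 0.606 against 0.453, and 0.0325 against 0.0261. MCA205 minus Control had r = -0.725 with the vaccine minus MCA205 (simulated -0.531, covariance -0.0558 against -0.0319) and -0.635 with the antibody minus MCA205 (simulated -0.497, covariance -0.0490 against -0.0287). All observed r lay inside the simulated ranges. Groups of 3 cannot be divided into sets with at least 2 libraries each, so part of each excess may come from the shared libraries; 0 genes were called by limma in both comparisons of any pair.

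Each comparison of 3 against 3 has 10 splits, too few for a share under 0.05. For genes called, the real count and the highest of the other splits were 1 and 0 for MCA205 minus Control, 0 and 5 for MCA205_VAC minus MCA205, 0 and 1 for MCA205_PD1 minus MCA205, 0 and 1 for MCA205_VAC minus MCA205_PD1, and 0 and 0 for each treated group against Control. A count as large came from 1 split in the first comparison and from 10 in each of the others. For lists, the real count and the highest other were 10 and 17, 7 and 20, 12 and 22, 10 and 14, 14 and 15, and 13 and 18, with 5, 6, 5, 6, 3 and 5 splits as large, in the order MCA205 minus Control, vaccine and antibody minus MCA205, vaccine minus antibody, and vaccine and antibody minus Control. For the vaccine and Control, whose numbers may pair, the 4 splits that part all 3 pairs gave 12 to 15 lists, the real one 14. The 6 that part 1 pair gave 4 to 12.

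The corpus luteum score varied widely between libraries. The study group took 0.338 of its variance, a share that shuffled labels often reached (permutation p = 0.312). The group is neither shown nor excluded as a cause. A different share of luteal tissue in the piece sampled, or a different stage of the cycle, may account for the spread: oocyte, germ cell and surface epithelium scores all moved against the luteal score, the weakest with a Spearman rho of -0.441 (permutation p = 0.153, adjusted 0.241). The cycle stage was not tested and stays open beside the treatment.

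The interferon gamma list was higher with the PD-1 antibody, most of all in replicate 3. That library ranked 1 of 12 for T cell, macrophage and MHC class II markers, at 0.570, 0.434 and 0.964 against at most 0.112, 0.259 and 0.241 elsewhere, so more immune cells in the tissue of replicate 3 is a candidate explanation. In RNA of a tissue these ranks cannot tell more cells from more expression per cell. Whether 1 library carries the pattern could not be decided, as the other 2 antibody libraries averaged 0.123 against -0.116 for the 9 libraries of other groups (exact p = 0.145 over 55 choices). A piece of lymph node in the sample was not decided either. B cell markers lay 0.422 above the median of the other 11 libraries and lymph node stroma markers 0.0888 above. These scores rest on 3 and 2 tested genes, and MCA205 replicate 3 was nearly as high for B cell markers (0.308 against 0.349). An effect of the antibody stays open beside these.

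For the chaperone difference between MCA205 and treated ovaries, a different luteal share was tested for the vaccine against MCA205 only. With the corpus luteum covariate the chaperone median was 0.296 and without it 0.286, so it did not shrink. The error of this change was not worked out, and the antibody comparison was not tested. Time of day at collection could not be decided. The median log2 fold change of 8 clock output genes was -0.12 for the vaccine and -0.19 for the antibody against MCA205, with 7 of 8 lower in each, and their antiphase genes were higher in 4 of 4 (medians 0.15 and 0.091). The standard error of such a difference between groups is 0.274, so a shift of 0.5 is not excluded. Stress during dissection could not be decided either: chaperones and immediate early genes had a Spearman rho of 0.077 over 12 libraries (r = 0.213, permutation p = 0.816 for rho and 0.515 for r, adjusted 0.898 and 0.534 over 11 relations; r = 0.257 without the 2 farthest libraries). A treatment effect, time of day and dissection stress all stay open, and luteal share is not excluded.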
